A study of Mus musculus with 27 samples.

How the data were processed

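Adult neurogenesis of the mouse was profiled at 4 stages: neural stem cells (NSC) and early neuroblasts (ENB) from the subventricular zone, and late neuroblasts (LNB) and neurons (Neuron) from the olfactory bulb. Per the labels, male mice aged 8 to 12 weeks carried a tamoxifen-inducible Cre recombinase driven by Tlx (Nr2e1) or by Dcx, an eYFP reporter, and RiboTag, an allele that adds an HA epitope to the ribosomal protein Rpl22 in recombined cells. Tamoxifen was given at 200 mg per kg. Total mRNA came from 200 to 500 eYFP-positive cells that were sorted from the dissociated tissue of 1 to 2 mice per replicate. Ribosome-bound mRNA came from anti-HA immunoprecipitation of whole tissue homogenate, with no sorting step, and the control was the same immunoprecipitation from tissue without the HA tag. Both kinds of library hold polyadenylated mRNA amplified by Smart-seq2, so the ribosome-bound libraries measure which mRNAs are attached to tagged ribosomes and not where ribosomes sit on them.

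The 27 libraries fall into 10 groups by their titles, and 0 data columns were left without a sample. The 2 Neuron ribosome-bound libraries were grouped by their titles and descriptions, although 1 of their label fields reads total mRNA and they carry the text of the sorting protocol. ENB and LNB replicates share some animals, since both tissues of an animal were used. In ribosome-bound mRNA, replicates 1 and 2 of ENB and LNB come from the same animals under the same numbers, whereas in total mRNA the shared animals carry different numbers. Correlations between libraries of the same number, after removing each group's mean, ran from -0.11 to 0.066 over 18 pairs in total mRNA. In ribosome-bound mRNA they ran from -0.013 to 0.091 over 12 pairs. In groups of 2 libraries the deviations are mirror images, so these 12 values are not independent and cannot exclude pairing. The numbers were not used as pairs in the tests and entered only as an alternative. The 24 pairs of replicates had Spearman correlations from 0.875 to 0.983, and none looked like a copy of another library.

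The deposited raw counts are whole-number read counts per Ensembl gene, and the labels do not say which tool made them. The deposited expected counts are estimated counts per gene that are not whole, and the deposited TPM values sum to 1000000 in each library by the authors' scaling. Per the submitters' processing notes, RSEM 1.2.21 and Bowtie2 2.2.6 were run on GRCm38. Of the 45195 genes, 44548 matched a symbol in the GRCm38.p6 annotation, from which chromosome, start and end are given, and 56 symbols stand for more than 1 gene, which is why 39 genes are measured for a list of 38 neuroblast symbols. A further 92 TPM entries without a gene ID were not used. The library totals ranged from 5225929 to 15994635 counts.

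Tests were run on the raw counts in R 4.3.3 with edgeR 4.0.16. Each fit used TMM scale factors, the filterByExpr filter and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 12 total mRNA libraries formed 1 fit, and the 15 immunoprecipitation libraries, 9 with HA and 6 controls, formed another. The 21 libraries of both kinds without the controls formed the fit for the interaction, which asks whether the change between 2 stages differs between ribosome-bound and total mRNA. This gave 13 comparisons: 3 consecutive steps in total mRNA, 3 in ribosome-bound mRNA, 3 in ribosome-bound relative to total mRNA, and 4 of a stage's immunoprecipitate against the control of its tissue. Log2 fold changes are given with the standard error implied by the F statistic, and levels are CPM (counts scaled to the same library total) with TMM. Where all libraries of a group were at 0, a fold is given only as a bound, computed against 3 counts over the libraries of that group.

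The 26 gene lists, the 27-gene marker panel, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered neural stem cell and astrocyte-lineage genes, stem cell transcription factors, activation and commitment genes, cell cycle genes, neuroblast genes, synapse and mature neuron genes, olfactory bulb interneuron subtype genes, cytosolic ribosomal proteins, other mRNAs with a terminal oligopyrimidine (TOP) start, mTOR pathway, oxidative phosphorylation, glycolysis, fatty acid oxidation and lipid synthesis, and immediate early and dissociation stress genes. Other lists held markers of mature astrocytes, oligodendrocytes, their precursors, microglia, endothelial cells, mural cells and fibroblasts, ependymal cells, striatal projection neurons, mitral and other glutamatergic neurons, olfactory ensheathing cells and sensory axons, and blood cells. A list of 13 mitochondrially encoded genes had no entry under its symbols and was not analysed here. Some genes stand in more than 1 list, for example Sox2, Id2 and Nr2e1 in both stem cell lists. Some genes are not reported here. Lists were tested with camera of limma 3.58.1 at the preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. A list needed at least 5 measured members.

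Named genes are the panel, the 5 largest rises and falls of each step (3 against a control) among genes past the threshold with a mean log2 CPM of at least 4 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest adjusted p. Genes known only by an identifier were left out of the second set. The labels give the second index sequence of each library's barcode, and values within libraries of 1 index are given beside the pooled ones where both stages have such libraries. The alternatives were DESeq2 1.42.0, RLE scale factors, no low-count filter, expected counts, limma on log2 TPM with a pseudocount of 1, the replicate number as a block, the index as a term, 1 fit of all 27 libraries, fits of the compared groups alone, and each library left out in turn. For the ribosome-bound steps the genes above the control in both stages, the change relative to each tissue's control and an animal block for ENB and LNB were also tried. Fits of 1 index alone, fits without the genes Gm42418 and CT010467.1, which overlap ribosomal RNA, and the lists with each library left out were added after the data were seen.

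The tests were tested on simulated data with 200 genes changed by a true log2 value of 2. Only the step from NSC to ENB and NSC against the control were simulated. The tests recovered 107 in total mRNA with 11 false calls, 169 in ribosome-bound mRNA with 6, 60 for the interaction with 4, and 179 against the control with 6.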

Results

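The 27 libraries profile 4 stages of adult neurogenesis in the mouse, from neural stem cells (NSC) and early neuroblasts (ENB) of the subventricular zone to late neuroblasts (LNB) and neurons (Neuron) of the olfactory bulb. Total mRNA of sorted eYFP-positive cells has 3 libraries per stage. Ribosome-bound mRNA, recovered through HA-tagged Rpl22, has 2 libraries each for NSC, ENB and Neuron and 3 for LNB. The no-HA controls have 3 libraries from the subventricular zone and 3 from the olfactory bulb, and they give the background of the immunoprecipitation. Depth ran from 5225929 to 15994635 counts per library in total mRNA, from 6325479 to 13316334 in ribosome-bound mRNA and from 5960357 to 9120659 in the controls. The p-values measure the spread between libraries, each from 1 to 2 mice in total mRNA, and ENB and LNB share some animals. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and gene lists were compared with other genes by camera. For the genes named below as changed between stages or against the control, all libraries of the higher group lay above all of the lower, which chance gives more often the fewer the libraries. Slc17a6 is the exception and is given with its overlap. Where leaving out 1 library ended the call of a named gene or list, that library and the adjusted p without it are given. Genes named only for opposite directions in total and ribosome-bound mRNA are not covered by these statements.

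The step from NSC to ENB asks which transcripts change as stem cells become migrating neuroblasts. In total mRNA Nr2e1 (ENSMUSG00000019803, GRCm38.p6 chromosome 10, 42561963 to 42583590), the orphan nuclear receptor that maintains adult stem cells, went from 273 ± 55.8 to 19.2 ± 9.07 CPM (SD, n = 3 each), a log2 change of -3.82 ± 0.78 (adjusted p = 0.012). The astrocyte-lineage glutamate transporter Slc1a3 changed by -3.71 ± 0.71 on the log2 scale and the neuropeptide-processing enzyme Cpe by -2.99 ± 0.47. Of 35 neural stem cell and astrocyte-lineage genes 22 fell (25 adjusted over the list alone, median -2.99, adjusted p = 0.31 with an estimated correlation), and of 30 stem cell transcription factors 13 fell and 2 rose (17 and 2 adjusted over the list alone, median -2.08, adjusted p = 0.31 with an estimated correlation). Dcx (ENSMUSG00000031285, chromosome X, 143855842 to 143933396), a microtubule-binding protein of migrating neuroblasts, rose from 158 ± 30.4 to 1225 ± 250 CPM, a change of 2.97 ± 0.28 (adjusted p = 0.00055). Nr2e1 and Dcx also drive the Cre that labelled the cells, so their changes are not independent of how the cells were chosen. Tubb3 and Tubb2b, neuronal tubulins, rose by 2.35 ± 0.25 and 2.27 ± 0.22, the synaptic adhesion gene Nrxn3 by 2.38 ± 0.24 and the tubulin regulator Stmn2 by 2.62 ± 0.27. All 33 neuroblast genes past the threshold, of 39, were higher (39 adjusted over the list alone, median 2.27). Matn4 (ENSMUSG00000016995, chromosome 2, 164389393 to 164405160), an extracellular matrix gene, had the largest rise among named genes, 5.87 ± 1.13, while Chrdl1, a BMP antagonist, was at least 190-fold and Cpne6 at least 103-fold lower, since ENB had no counts.

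Glycolysis genes moved with the stem cell genes, 10 of 19 lower and 1 higher (12 and 1 adjusted over the list alone, median -1.18, adjusted p = 0.41 with an estimated correlation), led by Aldoa at -2.66 ± 0.31 and Eno2 at -2.96 ± 0.54. Lipid metabolism followed, with 8 of 30 fatty acid oxidation and lipid synthesis genes lower and 1 higher (16 and 1 adjusted over the list alone, median -1.02, adjusted p = 0.44 with an estimated correlation). Markers of other cells moved in both directions. Mature astrocyte genes were lower in 6 of 16 (13 adjusted over the list alone, median -3.00, adjusted p = 0.41 with an estimated correlation) and ependymal genes in 5 of 12 (8 adjusted over the list alone, median -3.00 with genes at 0 set to their bound), whereas oligodendrocyte precursor genes were higher in 4 of 10 (5 adjusted over the list alone, median 3.34, adjusted p = 0.41 with an estimated correlation), among them Lhfpl3 at 3.79 ± 0.72. Cell cycle genes had a median of -0.28 and Mki67, a proliferation marker, 0.06 ± 0.87 (adjusted p = 0.98). The transcription factors Sox2 and Pax6, at -0.60 ± 0.28 and 0.79 ± 0.41, had adjusted p of 0.18 and 0.24. Cytosolic ribosomal protein mRNAs had a median of 0.26, with an adjusted list p of 0.012 that was 0.298 without NSC replicate 1 and 0.794 without ENB replicate 2, and adjusted p = 0.80 with an estimated correlation. Immediate early and dissociation stress genes were lower in 2 of 26 (3 adjusted over the list alone, median -0.77, adjusted p = 0.60 with an estimated correlation), a call that ended without NSC replicate 2 (adjusted p = 0.151).

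In all, 1772 of 17592 genes changed in total mRNA from NSC to ENB, 871 up and 901 down. With an estimated correlation the calls of the neuroblast list (adjusted p = 0.046) and the ependymal list (adjusted p = 0.046) held, and no other list above did. Leaving out any 1 of the 6 libraries lowered the count, to between 721 without ENB replicate 3 and 892 without NSC replicate 1, and Nr2e1 then had adjusted p of 0.0536 without ENB replicate 1 and 0.0513 without ENB replicate 2. Within index GTAAGGAG, with 1 ENB library, and within ACTGCATA, with 1 NSC library, the neuroblast median was 2.04 and 2.31 and the stem cell and astrocyte-lineage median -2.58 and -3.14.

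From ENB to LNB, neuroblasts leave the subventricular zone and enter the olfactory bulb, and the comparison asks what changes on the way. Cell division genes fell in total mRNA: the mitotic kinesin Kif11 at -3.18 ± 0.40, the cyclins Ccna2 and Ccnd2 at -2.61 ± 0.36 and -2.08 ± 0.32, and the mitotic kinase Cdk1 at -3.20 ± 0.47. Of 40 cell cycle genes 23 were lower (39 adjusted over the list alone, median -3.07), as were 3 of 19 activation and commitment genes (11 adjusted over the list alone, median -1.09). Mki67, at -3.31 ± 0.95, had an adjusted p of 0.079. Dcx, at 1227 ± 415 CPM in LNB, changed by -0.03 (adjusted p = 0.98), and the neuroblast list had a median of -0.33 with 1 of 39 lower (none adjusted over the list alone, adjusted p = 0.49 with an estimated correlation). Chrdl1 (ENSMUSG00000031283, chromosome X, 143285674 to 143394263) was at least 1448-fold higher in LNB. The cadherin Cdhr1, a mitral cell marker, rose by 6.54 ± 0.79 and the glycolytic enzyme Aldoa by 2.10 ± 0.31. Of 16 mature astrocyte genes 13 were higher (16 adjusted over the list alone, median 3.94, adjusted p = 0.127 with an estimated correlation). So were 11 of 35 stem cell and astrocyte-lineage genes (19 adjusted over the list alone, median 2.24, adjusted p = 0.38 with an estimated correlation), among them Slc1a3 at 4.09 ± 0.72. Other markers of bulb tissue were higher too. These were 3 of 11 ensheathing and sensory axon genes (7 adjusted over the list alone, median 4.41, adjusted p = 0.11 with an estimated correlation) and 2 of 11 mitral and other glutamatergic neuron genes (6 adjusted over the list alone, median 3.34 at the bounds, adjusted p = 0.115 with an estimated correlation). They also included 1 of 9 endothelial genes (6 adjusted over the list alone, median 4.82 at the bounds, adjusted p = 0.41 with an estimated correlation) and 1 of 7 mural and fibroblast genes (2 adjusted over the list alone, median 3.34, adjusted p = 0.25 with an estimated correlation). The glutamatergic, endothelial and mural medians rest on few counts. In ENB and LNB the mean log2 CPM was -1.40 and 1.58 for glutamatergic genes and -1.45 and 0.12 for mural genes. For endothelial genes it was -1.53 and 1.07, with an SD of 2.55 over the LNB libraries. The ensheathing list was higher, at 1.63 and 4.32. Immediate early and dissociation stress genes were lower in 2 of 26 (2 adjusted over the list alone, median -0.43, adjusted p = 0.41 with an estimated correlation). Oligodendrocyte genes had a median of -0.54 and microglia genes of 0.69, with adjusted list p of 0.48 and 0.26.

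The number of genes changed from ENB to LNB in total mRNA was 663, 493 up and 170 down. It lay between 96 without ENB replicate 3 and 163 without LNB replicate 3 when any library other than LNB replicate 2 was left out, and was 1643 without that one. Slc1a3 had adjusted p of 0.0742 without ENB replicate 1, 0.0834 without ENB replicate 3 and 0.0512 without LNB replicate 1. The replicate number as a block gave 205 genes and the second index as a term 155. The cell cycle and activation lists held with an estimated correlation (adjusted p = 0.037 each), and no other list above did. The neuroblast list lost its call without LNB replicate 3, at a median of -0.12 and an adjusted p of 0.136. Within index GTAAGGAG, with 1 ENB library, and within ACTGCATA, with 1 LNB library, the cell cycle median was -2.65 and -2.85, and that of the astrocyte genes 3.77 and 1.76.

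From LNB to Neuron, migrating cells settle in the bulb as interneurons, and total mRNA shows which programs close and open. Dcx fell by 2.74 ± 0.28, to 189 ± 37.8 CPM. Sox11 (ENSMUSG00000063632, chromosome 12, 27334268 to 27342718), a factor of immature neurons, fell by 6.05 ± 0.49 (adjusted p = 4.6e-05). Cd24a, a surface marker of neuroblasts, was at -4.21 ± 0.37 and Dlx2, a fate factor of bulb interneurons, at -3.95 ± 0.35. St8sia2 (ENSMUSG00000025789, chromosome 7, 73939119 to 74013727), which makes the polysialic acid of migrating neuroblasts, was at least 1310-fold lower. Of 39 neuroblast genes 32 were lower and 1 higher (34 and 2 adjusted over the list alone, median -1.97, adjusted p = 0.126 with an estimated correlation). Sox2 (ENSMUSG00000074637, chromosome 3, 34649995 to 34652461) went from 83.0 ± 5.89 to 19.2 ± 6.82 CPM, a change of -2.17 ± 0.29 (adjusted p = 0.00066). Pax6 went from 173 ± 33.8 to 37.2 ± 26.1, a change of -2.27 ± 0.42 (adjusted p = 0.0045). The stem cell transcription factors Nfix, Nfib and Nfia fell, at -2.81 ± 0.30, -2.62 ± 0.32 and -1.84 ± 0.28. Of the 30 in their list 10 were lower (13 lower and 1 higher adjusted over the list alone, median -1.62, adjusted p = 0.18 with an estimated correlation). Mature astrocyte genes had a median of -1.24 at this step, with an adjusted list p of 0.10 by camera. Activation and commitment genes were lower in 9 of 19 (11 adjusted over the list alone, median -1.74, adjusted p = 0.126 with an estimated correlation) and cell cycle genes in 15 of 40 (24 adjusted over the list alone, median -2.12, adjusted p = 0.18 with an estimated correlation). The vesicle fusion genes Nsf, Vamp2 and Snap25 rose by 2.71 ± 0.31, 1.97 ± 0.28 and 3.50 ± 0.66. So did the vesicle proteins Syp and Syt1 by 2.83 ± 0.43 and 3.51 ± 0.66, and Rbfox3, the NeuN antigen of mature neurons, by 3.06 ± 0.47. Of 42 synapse and mature neuron genes 24 were higher and 1 lower (32 and 1 adjusted over the list alone, median 2.60, adjusted p = 0.126 with an estimated correlation). Of 18 bulb interneuron subtype genes 3 were higher and 3 lower (9 and 3 adjusted over the list alone, median 2.54, adjusted p = 0.18 with an estimated correlation). The calcium-binding genes Calb2 and Scgn were at 4.18 ± 0.74 and 5.78 ± 1.29.

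Genes of the protein synthesis machinery fell at the same step. Of 79 cytosolic ribosomal protein mRNAs 75 were lower in Neuron total mRNA (78 adjusted over the list alone, median -1.71, adjusted p = 1.7e-49, adjusted p = 0.126 with an estimated correlation), including Rplp0 at -2.07 ± 0.21, Rpl32 at -2.28 ± 0.25 and Rps26 at -2.71 ± 0.30. Other mRNAs with a TOP start were lower in 14 of 25 (19 adjusted over the list alone, median -0.89, adjusted p = 0.126 with an estimated correlation), with the splicing regulator Hnrnpa1 at -2.18 ± 0.24 and the elongation factor Eef1a1 at -1.30 ± 0.20. Glycolysis genes were higher in 7 of 19 (10 adjusted over the list alone, median 0.89, adjusted p = 0.27 with an estimated correlation), led by Eno2 at 3.43 ± 0.54. Of the 2580 genes that changed, 937 rose and 1643 fell, and the median of all genes was -0.18. With RLE scale factors that median was -0.014 and 1193 of 2465 genes rose. Leaving out LNB replicate 1 gave 1565 genes, and each other library between 1945 and 2337. No list call at this step held with an estimated correlation. Genes that overlap ribosomal RNA took 3.98 to 14.4% of counts in total mRNA libraries of index ACTGCATA and 0.43 to 1.83% in those of GTAAGGAG. All Neuron libraries carry index ACTGCATA, as does 1 of LNB, and without these genes 2381 changed, 1041 up. Within that index the medians were -2.47 for neuroblast genes, 2.16 for synapse genes and -1.41 for ribosomal proteins, all 79 below 0. The stem cell and astrocyte-lineage list was at -1.16 pooled (8 of 35 lower, 10 adjusted over the list alone, adjusted p = 0.64 with an estimated correlation) and at 1.17 within the index, and it lost its call without LNB replicate 3 (adjusted p = 0.0889) or Neuron replicate 3 (0.0553).

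Markers of other cells were also higher in Neuron total mRNA, in few genes per list. Oligodendrocyte genes were higher in 1 of 15 (1 adjusted over the list alone, median 3.13, adjusted p = 0.598 with an estimated correlation). Mitral and other glutamatergic neuron genes were higher in 2 of 11 (5 adjusted over the list alone, median 2.94, adjusted p = 0.154 with an estimated correlation). Striatal genes were higher in 1 of 13 (3 adjusted over the list alone, median 1.04, adjusted p = 0.252 with an estimated correlation), and the list lost its call without LNB replicate 3 (adjusted p = 0.0708) or Neuron replicate 3 (0.0551). Oligodendrocyte precursor genes were higher in 1 of 10 (1 adjusted over the list alone, median 1.17, adjusted p = 0.68 with an estimated correlation). That list lost its call with RLE scale factors and without LNB replicate 1 (adjusted p = 0.119), LNB replicate 2 (0.164), Neuron replicate 1 (0.0561) or Neuron replicate 3 (0.106).

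**Figure D1:**
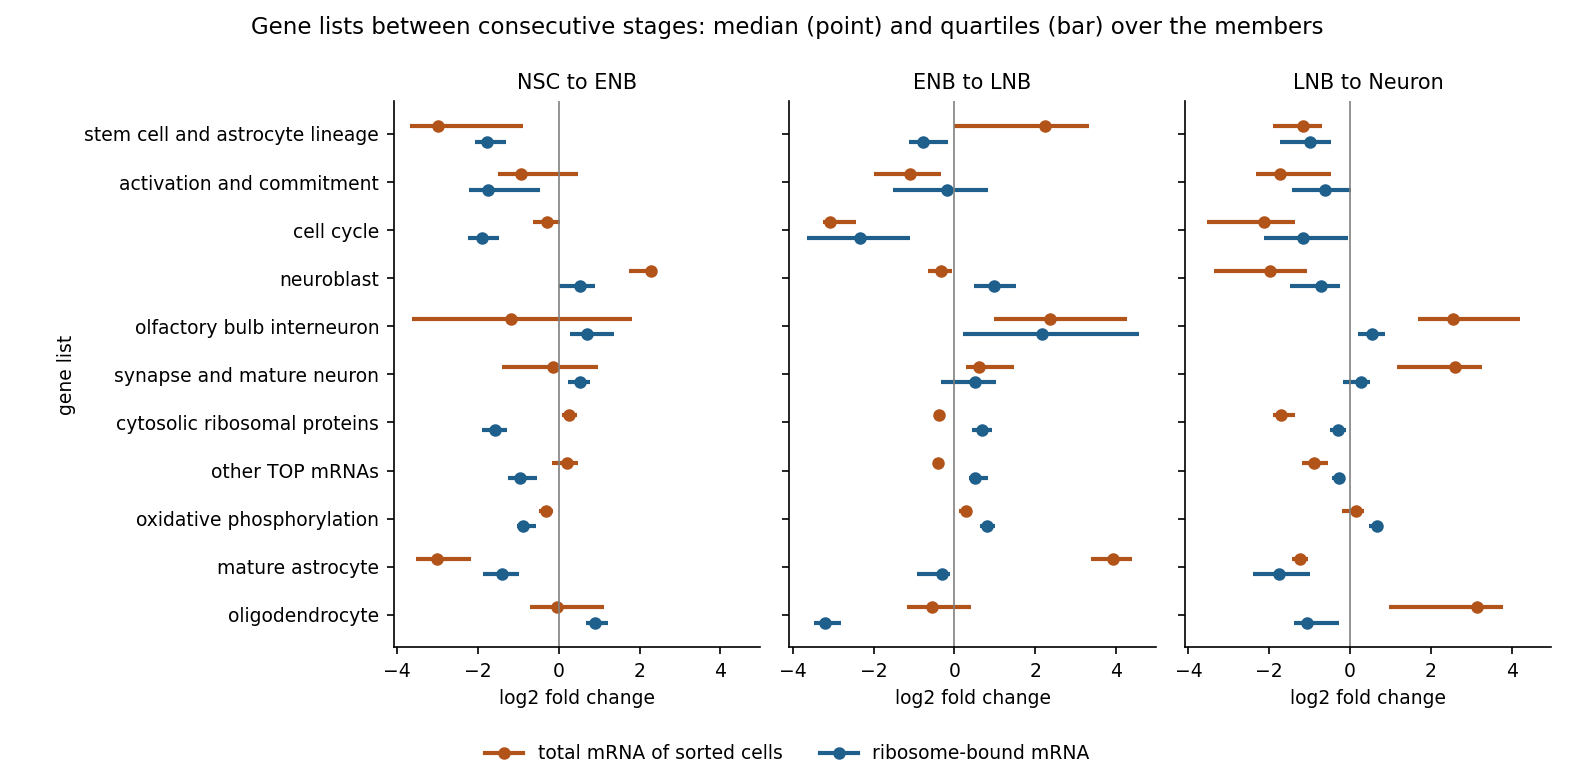
Median log2 fold change (horizontal axis, points) and quartiles (bars) over the members of 11 gene lists (vertical axis) at the 3 consecutive steps, in total mRNA of sorted cells and in ribosome-bound mRNA. From NSC to ENB the ribosomal protein median was 0.26 in total and -1.59 in ribosome-bound mRNA, and from LNB to Neuron it was -1.71 and -0.30.

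The immunoprecipitates came from whole tissue, so each was compared with the no-HA control of its tissue to ask which mRNAs lay above background. NSC immunoprecipitates held stem cell and division genes above the subventricular control. Higher were the radial glia genes Fabp7 and Vim, by 3.39 ± 0.34 and 3.09 ± 0.41, the growth factor receptor Egfr by 2.41 ± 0.27, and the replication factors Pcna and Mcm2 by 2.74 ± 0.24 and 4.25 ± 0.49. Nr2e1 was higher by 2.93 ± 0.64 and Sox2 by 1.94 ± 0.37, with adjusted p of 0.0073 and 0.0036 and of 0.0712 and 0.0686 without NSC replicate 2. Of 40 cell cycle genes 36 were higher (37 adjusted over the list alone, median 3.27). Of 35 stem cell and astrocyte-lineage genes 28 were higher and 1 lower (31 and 1 adjusted over the list alone, median 1.82). Of 30 stem cell transcription factors 14 were higher (17 adjusted over the list alone, median 1.39). Of 19 activation genes 14 were higher (16 adjusted over the list alone, median 2.65). These 4 held with an estimated correlation (adjusted p = 0.0047, 0.0093, 0.034 and 0.0019). Lipid genes, 21 of 30 higher (23 higher and 1 lower adjusted over the list alone, median 1.29), had an adjusted p of 0.11 with an estimated correlation. Mature astrocyte genes were higher too, 10 of 16 (11 adjusted over the list alone, median 1.25, adjusted p = 0.17 with an estimated correlation). So were neuroblast genes, 19 of 39 with 1 lower (21 and 5 adjusted over the list alone, median 1.12, adjusted p = 0.23 with an estimated correlation). Th, the dopamine synthesis enzyme, was at least 19.6-fold lower in NSC than in the control. The count was 2925 genes, 1668 up and 1257 down, and it was 1050 without NSC replicate 2, 1620 without control replicate 2 and 1389 without control replicate 3. Within index AGAGTAGA, with 1 control library, the cell cycle median was 3.88. The second index as a term gave 1176 genes.

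ENB immunoprecipitates held neuroblast genes above the same control, with Dcx at 2.71 ± 0.35, the neurite growth gene Dpysl3 at 3.18, Igfbpl1 at 3.38, the progenitor factor Sox4 at 3.55 ± 0.45 and the interneuron factor Sp8 at 3.99 ± 0.62. Of 39 neuroblast genes 22 were higher (30 adjusted over the list alone, median 1.57), with 6 of 19 activation genes (7 adjusted over the list alone, median 0.71) and 2 of 40 cell cycle genes (8 adjusted over the list alone, median 1.28). Cytosolic ribosomal protein mRNAs lay below the control, 64 of 79 lower (77 adjusted over the list alone, median -1.58, adjusted p = 2.2e-109), including Rpl23a at -2.12, Rps14 at -1.91 and Rps6 (ENSMUSG00000028495, chromosome 4, 86854099 to 86857367) at -1.16 ± 0.21. Oligodendrocyte genes had a median of 0.03 and stem cell and astrocyte-lineage genes of 0.17 against the control, with adjusted list p of 0.69 and 0.18. The neuroblast, activation, ribosomal protein and cell cycle lists held with an estimated correlation, at adjusted p = 0.019 for the first 3 and 0.048 for the last. Only 290 genes differed, and leaving out ENB replicate 2 left 1, ENB replicate 1 193 and control replicate 3 170. All genes named here therefore lost their call without ENB replicate 2, with adjusted p of 0.0552 for Dpysl3, 0.0617 for Sox4, Igfbpl1 and Rpl23a, 0.07 for Rps14, 0.0707 for Dcx, 0.105 for Sp8 and 0.146 for Rps6, which also lost it without ENB replicate 1. The neuroblast median was 1.82 and the ribosomal protein median -2.00 within index AGAGTAGA, with 1 library on each side.

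LNB immunoprecipitates lay above the bulb control in neuroblast genes, 28 of 39 higher (33 adjusted over the list alone, median 1.47), among them Cd24a at 3.22 ± 0.40, Igfbpl1 at 3.85 ± 0.41 and Dpysl3 at 2.77 ± 0.34. Endothelial genes were lower in 6 of 14 (13 adjusted over the list alone, median -1.48), with the receptor Flt1 at -1.77 ± 0.28. So were mural and fibroblast genes in 5 of 14 (10 adjusted over the list alone, median -1.60) and ensheathing and sensory axon genes in 4 of 12 (8 adjusted over the list alone). These 4 lists held with an estimated correlation, at adjusted p = 0.026, 0.026, 0.017 and 0.017. Neuron immunoprecipitates lay above the same control in the interneuron genes Pcp4 (ENSMUSG00000090223, chromosome 16, 96467606 to 96525793), Penk and Synpr, by 3.04 ± 0.26, 2.45 ± 0.29 and 2.21 ± 0.29. They also did in the GABA genes Gad1 and Slc32a1, by 1.59 ± 0.25 and 2.00 ± 0.35, and in 69 of 74 oxidative phosphorylation genes (72 adjusted over the list alone, median 1.29, adjusted p = 0.065 with an estimated correlation). They lay below it in 24 of 35 stem cell and astrocyte-lineage genes, with 1 higher (27 and 1 adjusted over the list alone, median -2.18), in 12 of 14 endothelial genes (13 adjusted over the list alone, median -3.22) and in all 17 microglia genes (17 adjusted over the list alone, median -3.23, adjusted p = 0.099 with an estimated correlation). Gfap, an astrocyte filament, was at -3.19 ± 0.33 and the complement gene C1qb of microglia at -3.84 ± 0.54. Bulb interneuron subtype genes, 8 of 19 higher (10 adjusted over the list alone, median 0.71), held with an estimated correlation, as did the stem cell and astrocyte-lineage list (adjusted p = 0.045 each) and the endothelial list (0.023). Esr1 (ENSMUSG00000019768, chromosome 10, 4611989 to 5005633), the oestrogen receptor whose ligand-binding part is built into tamoxifen-inducible Cre, was higher by 7.36 ± 0.89 in LNB and by 6.79 ± 0.90 in Neuron.

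Against the bulb control 1918 genes differed in LNB, 1335 up and 583 down, and 5221 in Neuron, 2221 up and 3000 down. With RLE scale factors 663 of 1425 genes were up in LNB, and the median of all genes was -0.246 in place of -0.083. The LNB count was 829, 163 and 95 without LNB replicates 1, 2 and 3, and 1223 and 661 without control replicates 1 and 3. Control replicate 3 stood apart in Malat1, which took 4.10% of its counts against 0.65 and 0.63% in control replicates 1 and 2. The Neuron count was 2593 without Neuron replicate 2. The LNB neuroblast median was 1.10 within index TATCCTCT.

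**Figure D2:**
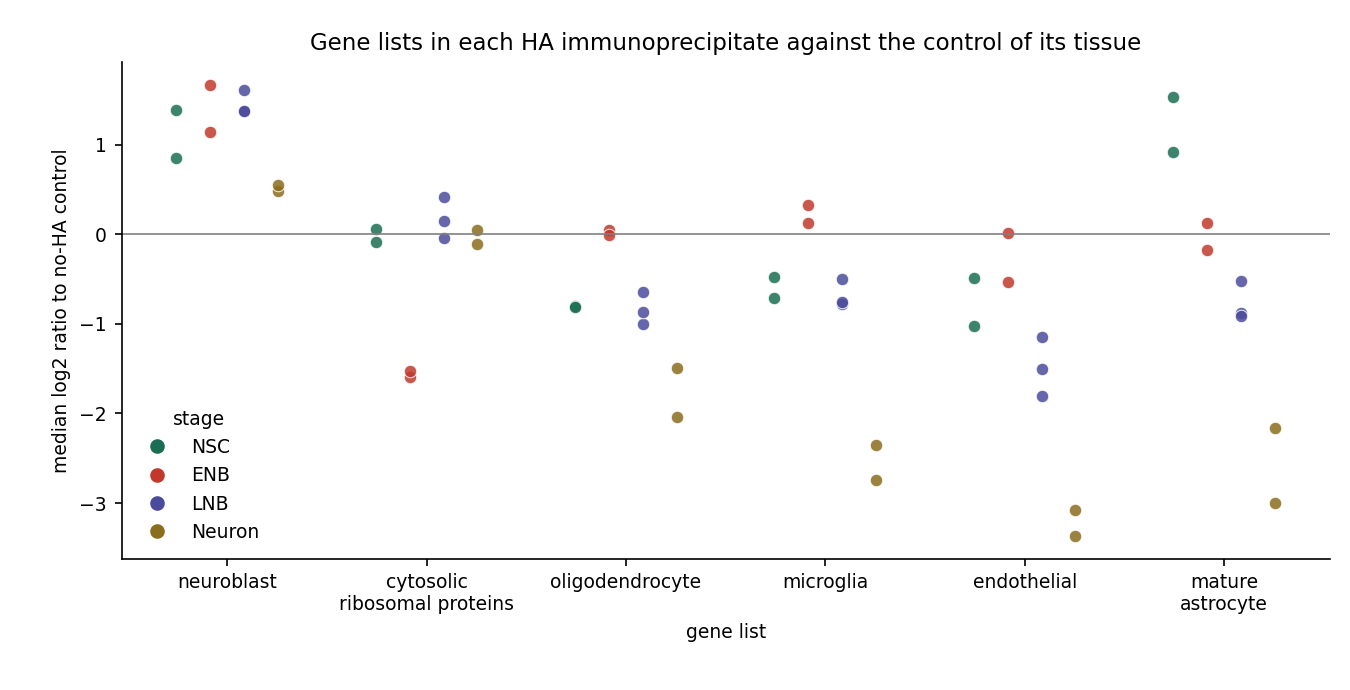
Median log2 ratio to the no-HA control of the same tissue (vertical axis) for 6 gene lists (horizontal axis), 1 point per immunoprecipitate, coloured by stage (2 libraries each for NSC, ENB and Neuron, 3 for LNB). The ENB libraries were at -1.59 and -1.53 for ribosomal protein genes and at 0.042 and -0.013 for oligodendrocyte genes, and the Neuron libraries at -3.08 and -3.37 for endothelial genes.

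In ribosome-bound mRNA the step from NSC to ENB compares the messages recovered with tagged ribosomes at commitment. Where ENB lay at the control level, a fall from NSC was a return to background. Fabp7 fell by 3.34 ± 0.39. The inhibitors of differentiation Id2 and Id3 were at -1.74 ± 0.26 and -1.99 ± 0.30, Egfr at -2.79 ± 0.31 and Pcna at -2.16 ± 0.27. Egfr stood at 14.3 ± 1.22 CPM (SD) in ENB against 18.1 ± 1.88 in the control, so it was at background. Of 35 stem cell and astrocyte-lineage genes 24 were lower and 1 higher (30 and 1 adjusted over the list alone, median -1.78). Of 19 activation genes 8 were lower (11 adjusted over the list alone, median -1.75) and of 40 cell cycle genes 15 (26 adjusted over the list alone, median -1.89). The stem cell and astrocyte-lineage list was near background in ENB, at a mean log2 CPM of 6.08 against 5.90 in the control. The activation list, at 4.63 against 3.66, and the cell cycle list, at 4.01 against 2.69, stayed above it. Sox2 went from 67.0 ± 26.95 to 14.5 ± 2.74 CPM (SD, n = 2 each), against 17.1 ± 2.73 in the control, a change of -2.23 ± 0.43 (adjusted p = 0.0069). It lost its call without NSC replicate 2 (adjusted p = 0.0634) or ENB replicate 2 (0.0645). Pax6 changed by -0.68 ± 0.62 (adjusted p = 0.52, and 0.0426 without NSC replicate 1). Th had no counts in NSC and 4.23 ± 0.77 CPM in ENB, at least 19.1-fold more, against 4.09 ± 1.77 in the control, so ENB lay at the control level. The prokineticin receptor Prokr2, which guides neuroblasts to the bulb, rose by 5.43 ± 0.81 and the homeobox gene Pbx3 by 1.63 ± 0.29. Dcx, at 1.42 ± 0.38 (adjusted p = 0.032), lost its call without NSC replicate 1 (0.197) or ENB replicate 2 (0.372). The neuroblast list, with 5 of 39 higher and 1 lower (11 and 1 adjusted over the list alone, median 0.53), lost its call without ENB replicate 2 at a median of 0.03 (adjusted p = 0.394) and had adjusted p = 0.43 with an estimated correlation.

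By number of genes, though not by median, the largest group to fall was that of the cytosolic ribosomal proteins. Of 79 mRNAs 72 were lower (77 adjusted over the list alone, median -1.59, adjusted p = 6.5e-63, adjusted p = 0.058 with an estimated correlation), led by Rps15a at -2.05 ± 0.30 and Rpl8 at -2.12 ± 0.31. Other TOP mRNAs were lower in 14 of 25 (16 adjusted over the list alone, median -0.96, adjusted p = 0.058 with an estimated correlation), with the elongation factor Eef1b2 at -1.38 ± 0.22, and oxidative phosphorylation genes in 26 of 74 (50 adjusted over the list alone, median -0.88, adjusted p = 0.157 with an estimated correlation). Genes of the mTOR pathway, which controls TOP mRNA translation, were lower in 2 of 37 (4 adjusted over the list alone, median -0.33, adjusted p = 0.088 with an estimated correlation), and the call ended without NSC replicate 2 (adjusted p = 0.074) and with RLE scale factors. Lipid genes were lower in 10 of 30 (23 adjusted over the list alone, median -1.05, adjusted p = 0.12 with an estimated correlation), including the lipid synthesis regulator Srebf1 at -1.74 ± 0.27. Mature astrocyte genes were lower in 9 of 16 (12 adjusted over the list alone, median -1.41, adjusted p = 0.12 with an estimated correlation). Oligodendrocyte genes, which the tag should not reach, were higher in 5 of 15 (8 adjusted over the list alone, median 0.89, adjusted p = 0.23 with an estimated correlation). Blood cell genes, 9 of them measured, had a median of -1.08, of 0.36 with genes at 0 set to their bound and an adjusted list p of 0.92.

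From NSC to ENB 1579 of 19066 genes changed in ribosome-bound mRNA, 655 up and 924 down. The count was 962 and 639 without NSC replicates 1 and 2, and 354 and 522 without ENB replicates 1 and 2. With an estimated correlation the stem cell and astrocyte-lineage list (adjusted p = 0.027), the activation list (0.027) and the cell cycle list (0.041) held. The other lists missed. Within index AGAGTAGA, with both NSC libraries and 1 of ENB, the ribosomal protein median was -1.60, 78 of 79 below 0, and that of the stem cell and astrocyte-lineage genes -1.88.

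At the step from ENB to LNB the tissue changes too, so for the lists and some genes the levels in the controls of both tissues are given. Th (ENSMUSG00000000214, chromosome 7, 142892779 to 142899995) rose by 6.11 ± 0.36 (adjusted p = 7.5e-08), from 4.23 ± 0.77 to 287 ± 4.18 CPM, and the controls had 4.09 ± 1.77 in the subventricular zone and 294 ± 55.4 in the bulb. Both stages thus lay at the level of their control. Calb2 rose by 7.65 ± 0.83 to 1446 ± 157, against 338 ± 113 in the bulb control, Scgn by 7.46 ± 0.68, the G protein subunit Gng4 by 5.21 ± 0.50 and the bulb interneuron factor Tshz1 by 2.83 ± 0.28. Of 19 subtype genes 12 were higher and 2 lower (13 and 2 adjusted over the list alone, median 2.17), at a mean log2 CPM of 4.95 in ENB and 7.23 in LNB against 4.58 and 6.67 in the controls. The GABA-synthesising enzyme Gad1 rose by 2.68 ± 0.28, from 359 ± 44.5 to 2246 ± 105 CPM, against 345 ± 63.8 and 1484 ± 402 in the controls. The interneuron factor Sp9 rose by 1.91 ± 0.31, with 19 of 39 neuroblast genes higher (24 adjusted over the list alone, median 0.99, adjusted p = 0.156 with an estimated correlation). Dcx rose by 1.64 ± 0.36 to 937 ± 179 CPM (n = 3), against 321 ± 27.7 in the bulb control, and lost its call without ENB replicate 1 (adjusted p = 0.0985). Pax6 (ENSMUSG00000027168, chromosome 2, 105668896 to 105698410) rose by 2.44 ± 0.60 to 91.3 ± 6.45, against 81.4 ± 6.14 in the bulb control and 21.5 ± 9.43 in the subventricular one, and lost its call without ENB replicate 1 (0.0876) or 2 (0.101). The topoisomerase Top2a fell by 4.25 ± 0.45 and the kinetochore gene Cenpf by 3.46 ± 0.51, with 21 of 40 cell cycle genes lower and 1 higher (27 and 1 adjusted over the list alone, median -2.33). Ribosomal protein mRNAs were higher in 20 of 79 (37 adjusted over the list alone, median 0.67, adjusted p = 0.41 with an estimated correlation), with Rps15a at 1.48 ± 0.27. Their mean log2 CPM was 6.52 in ENB and 7.14 in LNB against 8.00 and 7.04 in the subventricular and bulb controls, so LNB lay near its control and ENB below. Other TOP mRNAs were higher in 6 of 25 (8 adjusted over the list alone, median 0.52, adjusted p = 0.31 with an estimated correlation) and oxidative phosphorylation genes in 34 of 74 (55 adjusted over the list alone, median 0.81, adjusted p = 0.21 with an estimated correlation), with Uqcrb at 1.64 ± 0.30. The mTOR list was higher in 4 of 37 (4 adjusted over the list alone, median 0.47, adjusted p = 0.079 with an estimated correlation), without its call under RLE scale factors. In ENB and LNB, and then in the 2 controls, the mean log2 CPM was 7.34, 8.36, 5.71 and 6.87 for neuroblast genes and 4.01, 1.84, 2.69 and 1.39 for cell cycle genes. It was 7.07, 7.53, 7.35 and 7.03 for TOP, 6.68, 7.48, 7.05 and 6.92 for oxidative phosphorylation and 5.47, 5.87, 5.51 and 5.78 for mTOR genes.

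Striatal and myelin markers had the largest list medians at this step. Striatal projection neuron genes were lower in 13 of 14 (13 adjusted over the list alone, median -4.48), with the dopamine signalling genes Ppp1r1b, Drd1 and Adcy5 at -6.16 ± 0.24, -6.73 ± 0.33 and -3.79 ± 0.25. The same held for Scn4b (ENSMUSG00000046480, chromosome 9, 45138624 to 45154155), a sodium channel subunit, at -8.38 ± 0.65. The myelin genes Mal, Mog and Mbp fell by 3.30 ± 0.26, 3.65 ± 0.32 and 3.11 ± 0.28, and all 15 oligodendrocyte genes were lower (15 adjusted over the list alone, median -3.20). The controls differed between the tissues in the same way. The mean log2 CPM of the striatal list was 8.71 in ENB and 4.31 in LNB against 8.82 and 4.15 in the controls, and that of the oligodendrocyte list 8.42 and 5.31 against 8.33 and 6.20. Also lower were 6 of 16 ependymal genes (8 lower and 1 higher adjusted over the list alone, median -2.16, mean log2 CPM 2.94 and 0.58 against 3.07 and 1.19 in the controls) and 9 of 17 microglia genes (12 adjusted over the list alone, median -1.48, mean log2 CPM 5.71 and 4.29 against 5.56 and 5.02, adjusted p = 0.156 with an estimated correlation). Immediate early and dissociation stress genes were higher in 2 of 26 (2 adjusted over the list alone, median 0.85, mean log2 CPM 4.19 and 5.11 against 3.78 and 4.66, adjusted p = 0.44 with an estimated correlation), a call that ended without ENB replicate 2 (adjusted p = 0.08). The count of genes was 2452, 1298 up and 1154 down, and with RLE scale factors 953 of 2373 were up while the median of all genes went from 0.076 to -0.063. Replicates 1 and 2 of ENB and LNB share animals, and animal as a block gave 1217 genes. When the change in the no-HA controls between the tissues was subtracted, 76 genes passed. The count was 1271 and 1424 without ENB replicates 1 and 2, and 1621, 1408 and 1428 without LNB replicates 1, 2 and 3. With an estimated correlation the striatal (adjusted p = 2.8e-05), ependymal (0.0045), oligodendrocyte (0.0070), subtype (0.024) and cell cycle (0.045) lists held. Within index TATCCTCT, with 1 ENB library, the medians were 1.29 for neuroblast, -4.55 for striatal and 0.60 for ribosomal protein genes.

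From LNB to Neuron the ribosome-bound messages of immature neurons fell: Dcx by 2.00 ± 0.37 (adjusted p = 0.0057), Sox11 by 2.65 ± 0.46, Igfbpl1 by 4.04 ± 0.49 and Dpysl3 by 2.95 ± 0.41, with 11 of 39 neuroblast genes lower (15 lower and 1 higher adjusted over the list alone, median -0.71, adjusted p = 0.18 with an estimated correlation). In Neuron, Dcx stood at 237 ± 16.4 CPM (SD) against 321 ± 27.7 in the bulb control, and Sox11 at 97.4 ± 37.7 against 106.6 ± 33.5. Dcx and Sox11 thus returned to background. The neuroblast list stayed above it, at a mean log2 CPM of 7.27 against 6.87. Pcp4, a calmodulin regulator of bulb interneurons, rose by 2.64 ± 0.26 (adjusted p = 0.00016), with 2 of 19 subtype genes higher (4 adjusted over the list alone, median 0.54, adjusted p = 0.077 with an estimated correlation) and 2 of 42 synapse genes (4 adjusted over the list alone, median 0.26, adjusted p = 0.18 with an estimated correlation). Snap25 changed by 0.84 (adjusted p = 0.064, and 0.0424 with RLE scale factors) and Syt1 by 0.60 (adjusted p = 0.15). Oxidative phosphorylation genes were higher in 9 of 74 (37 adjusted over the list alone, median 0.68, adjusted p = 1.4e-30, adjusted p = 0.089 with an estimated correlation). Ribosomal protein mRNAs were lower in 2 of 79, with a median of -0.30 and an adjusted list p of 0.091, which was 0.0065 without LNB replicate 3 and 0.0118 without Neuron replicate 2, and also under 0.05 with the replicate number as a block. Sox2 changed by -0.83 ± 0.39 (adjusted p = 0.25) and Pax6 by 0.10 (adjusted p = 0.96). Gfap fell by 1.97 ± 0.31 and the astrocyte genes Aldh1l1 and Kcnj10 by 3.24 ± 0.37 and 2.38 ± 0.35, with 10 of 16 mature astrocyte genes lower (13 adjusted over the list alone, median -1.76, adjusted p = 0.077 with an estimated correlation). Against the bulb control the astrocyte list was at -2.16 and -3.00 in the Neuron libraries and between -0.91 and -0.52 in those of LNB. Microglia genes were at -2.35 and -2.74 against -0.78 to -0.50. These falls thus cannot be told from a lower background in the Neuron immunoprecipitates. Markers of other bulb cells moved with the astrocyte genes. These were 8 of 17 microglia genes (16 adjusted over the list alone, median -2.51, adjusted p = 0.077 with an estimated correlation) and 6 of 14 endothelial genes (7 adjusted over the list alone, median -1.49, adjusted p = 0.077 with an estimated correlation), all lower, as were 6 of 15 oligodendrocyte genes (8 adjusted over the list alone, median -1.07, adjusted p = 0.23 with an estimated correlation) and 3 of 14 mural genes (5 adjusted over the list alone, median -1.06, adjusted p = 0.077 with an estimated correlation).

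Among genes above the control in both stages only 1 changed in ribosome-bound mRNA from LNB to Neuron. The count over all genes was 787, 72 up and 715 down, with a median change of -0.15. It was 347, 432 and 476 without LNB replicates 1, 2 and 3, and 1199 and 387 without Neuron replicates 1 and 2. With an estimated correlation no list held. The mural list also lost its call without Neuron replicate 1 (adjusted p = 0.0507). LNB and Neuron ribosome-bound libraries share no index, and the Neuron libraries carry a label field that reads total mRNA.

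Ribosome-bound relative to total mRNA asks whether the 2 measures change by different amounts at a step. Translation control would appear here, but so would tissue background in the immunoprecipitates and other cells in the sorts. From NSC to ENB cytosolic ribosomal protein mRNAs were lower by this measure in 59 of 79 (76 adjusted over the list alone, median -1.65, adjusted p = 2.5e-72), with Rpl7 at -1.97 ± 0.28 and Rpl11 at -2.38 ± 0.35. Other TOP mRNAs were lower in 9 of 25 (14 lower and 1 higher adjusted over the list alone, median -0.81), including Eef1a1 (ENSMUSG00000037742, chromosome 9, 78478453 to 78481724) at -1.43 ± 0.27. Neuroblast genes, higher in total mRNA, were relatively lower in 9 of 39 (20 adjusted over the list alone, median -1.33, adjusted p = 0.085 with an estimated correlation), with Tubb2b at -2.59 ± 0.35, Stmn2 at -2.49 ± 0.38 and Tubb3 (ENSMUSG00000062380, chromosome 8, 123411553 to 123422015) at -2.17 ± 0.37. Aldoa was relatively higher by 2.76 ± 0.39, with 3 of 19 glycolysis genes (5 adjusted over the list alone, median 0.78, adjusted p = 0.55 with an estimated correlation). Sox2 changed by -1.45 ± 0.50 (adjusted p = 0.13), Pax6 by -1.28 ± 0.83 (adjusted p = 0.44) and Dcx by -1.37 ± 0.48 (adjusted p = 0.14, and 0.0357 without ENB ribosome-bound replicate 2). The count was 559 genes, 297 up and 262 down, but 43 with the second index as a term, and 459 or fewer without any 1 library. It was 324 and 345 without NSC total replicates 1 and 3, 191 without NSC ribosome-bound replicate 1, 281 without ENB ribosome-bound replicate 2, 56 without ENB ribosome-bound replicate 1 and 124 without NSC ribosome-bound replicate 2. The last 2 libraries, in this order, ended the calls of Tubb3 (adjusted p = 0.0532 and 0.0516) and Eef1a1 (0.0532 and 0.0602). The ribosomal protein (adjusted p = 0.040) and TOP (0.027) lists held with an estimated correlation. Ependymal genes were relatively higher in 3 of 16 (7 adjusted over the list alone) and held (adjusted p = 0.027). Mature astrocyte genes had a median of 1.58 (adjusted p = 0.63 with an estimated correlation). Immediate early and dissociation stress genes had a median of 1.32 (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.60 with an estimated correlation), and their call ended without NSC total replicate 2 (adjusted p = 0.129), ENB total replicate 3 (0.0599) or ENB ribosome-bound replicate 1 (0.054). Cell cycle genes were relatively lower in 1 of 40 (3 adjusted over the list alone, median -1.41, adjusted p = 0.27 with an estimated correlation).

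From ENB to LNB the direction turned for ribosomal protein, TOP and neuroblast genes. Ribosomal protein mRNAs were relatively higher in 19 of 79 (54 adjusted over the list alone, median 0.92, adjusted p = 0.19 with an estimated correlation), with Rpl27 at 1.72 ± 0.33. So were TOP mRNAs in 8 of 25 (14 adjusted over the list alone, median 0.84, adjusted p = 0.061 with an estimated correlation) and neuroblast genes in 9 of 39 (20 adjusted over the list alone, median 1.26, adjusted p = 0.128 with an estimated correlation), with Tubb3 at 1.99 ± 0.35. The immediate early genes Ier2 and Egr1 were relatively higher by 4.12 ± 0.58 and 3.33 ± 0.65, with 5 of 26 of their list (7 adjusted over the list alone, median 1.14, adjusted p = 0.15 with an estimated correlation), and the chaperone Hsp90aa1 by 1.55 ± 0.25. Mature astrocyte genes were relatively lower in all 16 (16 adjusted over the list alone, median -4.51, adjusted p = 0.108 with an estimated correlation), among them Mfge8 at -4.58 ± 0.90. So were stem cell and astrocyte-lineage genes in 17 of 35 (22 adjusted over the list alone, median -2.30, adjusted p = 0.15 with an estimated correlation), among them Slc1a3 at -4.52 ± 0.81. Striatal genes were relatively lower in 10 of 14 (12 adjusted over the list alone), with Pde10a at -4.81 ± 0.70. The controls differed in the same way for striatal genes, at a mean log2 CPM of 8.82 in the subventricular zone and 4.15 in the bulb. For mature astrocyte genes the median change was 3.94 in total mRNA and -0.31 in ribosome-bound mRNA. In all 1224 genes changed, 376 up and 848 down. Animal as a block gave 397, with animals shared as above, and the second index as a term 449. Fewer genes also passed among those above the control in both stages, and when the change in the controls was subtracted. The count was 321 without ENB ribosome-bound replicate 1, 2302 without LNB total replicate 2 and between 494 and 789 without ENB total replicate 3, ENB ribosome-bound replicate 2 or any other LNB library. Only the striatal list held with an estimated correlation (adjusted p = 0.0060).

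From LNB to Neuron ribosomal protein mRNAs were again relatively higher, 46 of 79 (71 adjusted over the list alone, median 1.35, adjusted p = 1.6e-51, adjusted p = 0.158 with an estimated correlation), with Rps23 at 2.21 ± 0.37 and Rps27a at 1.72 ± 0.29. Against the bulb control the list was at 0.14, 0.41 and -0.04 in the LNB libraries and at -0.10 and 0.04 in those of Neuron. The relative rise thus came mainly from the fall in total mRNA, at a median of -1.71, beside ribosome-bound levels near the control. Dlx2 was relatively higher by 3.12 ± 0.48 and Sox11 by 3.39 ± 0.61, with 13 of 39 neuroblast genes (18 higher and 1 lower adjusted over the list alone, median 1.23, adjusted p = 0.21 with an estimated correlation). Synapse genes were relatively lower in 14 of 42 (30 adjusted over the list alone, median -2.29, adjusted p = 0.158 with an estimated correlation), with Nsf at -2.51 ± 0.40 and Rbfox3 (ENSMUSG00000025576, chromosome 11, 118489760 to 118911597) at -2.73 ± 0.52. The mean log2 CPM of the synapse list in ribosome-bound mRNA was 7.87 in LNB and 8.04 in Neuron, near the 7.81 of the bulb control. In total mRNA it went from 5.13 to 7.61, so the relative fall came from the rise in total mRNA. Other-cell markers were relatively lower as well, with list calls at the preset correlation only. The median was -3.30 for oligodendrocyte genes (2 of 15 adjusted over the list alone, adjusted p = 0.38 with an estimated correlation). Of the glutamatergic neuron genes 4 passed over the list alone (adjusted p = 0.158 with an estimated correlation). The precursor list had a median of -2.17 (adjusted p = 0.569 with an estimated correlation) and lost its call without LNB total replicate 1 (adjusted p = 0.0577) or 2 (0.0945) or Neuron total replicate 3 (0.0701). Sox2 and Pax6 changed by 1.34 ± 0.47 and 2.37 ± 0.77, with adjusted p of 0.12 and 0.10, that of Pax6 being 0.0315 without Neuron total replicate 3. The count was 627, 291 up and 336 down. It was 78 and 199 without Neuron ribosome-bound replicates 2 and 1, 192, 234 and 261 without LNB ribosome-bound replicates 1, 2 and 3, and 332 without LNB total replicate 1. Sox11 lost its call without Neuron ribosome-bound replicate 2 (adjusted p = 0.0729) and Rbfox3 without replicate 1 (0.0686) or 2 (0.0978). No index is shared by all 4 groups at any relative step.

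**Figure D3:**
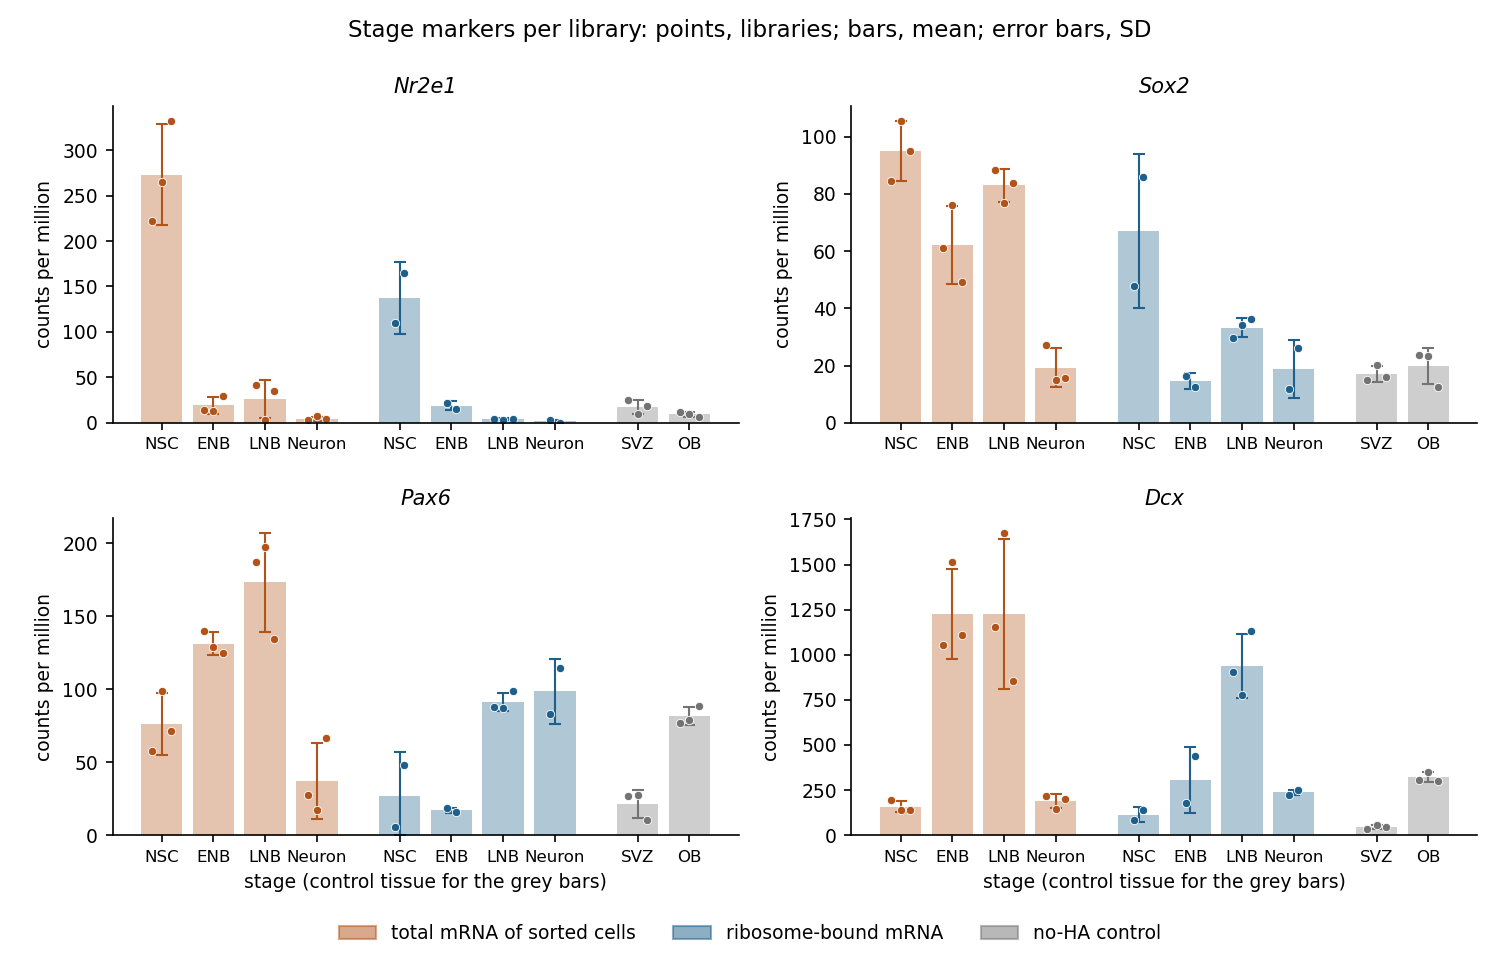
CPM (vertical axis) of Nr2e1, Sox2, Pax6 and Dcx by stage and control tissue (horizontal axis) in total mRNA (n = 3), ribosome-bound mRNA (n = 2 or 3) and no-HA controls (n = 3), with points for libraries, bars for means and error bars for SD. Pax6 reached 173 ± 33.8 in LNB total mRNA and 98.7 ± 22.4 in Neuron ribosome-bound mRNA, while Dcx reached 1227 ± 415 in LNB total mRNA.

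Across 16851 genes the Spearman correlation between the total and the ribosome-bound fold change was 0.254 from NSC to ENB, 0.013 from ENB to LNB and 0.286 from LNB to Neuron, and Pearson's was 0.184, 0.117 and 0.211. Genes are not independent replicates, so no p is given. Leaving out 1 library moved Spearman's value to between 0.199 and 0.255, -0.025 and 0.061, and 0.213 and 0.289. Of genes called in both measures 341, 182 and 191 were found at the 3 steps, of which 320, 141 and 181 had the same direction. Among those with opposite directions were Camk2a, a synaptic kinase, and Per3, a clock gene, at the first step, Dnmt1, the maintenance DNA methyltransferase, and Foxo1 at the next, and Enc1 and Rgs9 at the last.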

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

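The tests of background in the immunoprecipitates and of astrocytes in the LNB sort were chosen after the results were seen, and the others were not. Genes that rose in 1 measure and fell in the other, with the difference also passing, numbered 21 from NSC to ENB, 41 from ENB to LNB and 10 from LNB to Neuron. Total mRNA comes from sorted cells and ribosome-bound mRNA from whole tissue, so translation, cell composition and handling all differ between the 2 measures and these genes cannot tell them apart.

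Ribosomal protein mRNAs were lower in ENB than in NSC ribosome-bound mRNA. Untagged background cannot be the whole cause, since background would bring the list to the level of the no-HA control, and it lay below that control, at a median of -1.58 (-1.59 and -1.53 in the 2 libraries). Loss of short transcripts may contribute, and the matched lists cannot show how far. Of 10000 lists of other genes matched on length and expression 0 reached as low a median (centre -0.805). Yet the matched genes were longer, at a relative length of 0.324 against 0.218. They were also less abundant, at a median log2 CPM of 6.73 against 7.67. A closer match, at 0.283 and 7.15, again gave 0 lists. The list's members moved together (estimated correlation 0.62), whereas matched genes were drawn singly. A regression on length and expression leaves -0.892, 76 of 79 below 0. The library index, added as a term, leaves a median of -1.33 of -1.59, 62 genes lower and an adjusted list p of 4.4e-41, with adjusted p = 0.123 with an estimated correlation, which was 0.058 without the term. Lower loading of TOP mRNAs on ribosomes in ENB could lower the list only in the share of RNA from tagged cells. Markers of untagged cells show the background share that would remain. In both ENB libraries the oligodendrocyte, microglia, endothelial and striatal medians lay between -0.54 and 0.33 against the control. All were above -1.59 and -1.53. These values argue against lower loading as the whole cause. A difference in the ENB preparations themselves remains untested.

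Neuroblast genes were lower in ribosome-bound relative to total mRNA from NSC to ENB. Background RNA would fit, since oligodendrocyte genes stood at a median of 0.031 against the no-HA control in ENB and at -0.80 and -0.81 in the 2 NSC libraries, so that tagged ENB messages may be diluted. The library index, added as a term, leaves a median of -1.05 of -1.33 and an adjusted list p of 6.1e-13, with adjusted p = 0.295 with an estimated correlation, which was 0.085 without the term, while genes called lower went from 9 to 1. Delayed translation of neuroblast mRNAs in ENB would give the same sign and remains untested.

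Mature astrocyte genes were higher in LNB than in ENB total mRNA. Astrocytes in the LNB sort would fit, since the 10 most abundant other astrocyte-lineage genes had a median of 3.17 and all lay above 0, with Gja1 at 4.64, Fabp7 at 4.41 and Apoe, the most abundant at a mean log2 CPM of 12.5, at 3.93. These genes belong to the stem cell and astrocyte-lineage list, whose rise at this step was already known, so they add no independent support. A lower share of the main cell type could also raise markers of other cells. Oligodendrocyte, microglia and endothelial genes had medians of -0.54, 0.69 and 5.38 (4.82 at the bounds). The upper quartiles of the first 2, 0.40 and 2.58, lay below the lower astrocyte quartile of 3.39. These values cannot decide the question, since ENB were sorted from the subventricular zone and LNB from the bulb. In the no-HA controls of these tissues, oligodendrocyte genes had a mean log2 CPM of 8.33 and 6.20. Microglia genes had 5.56 and 5.02. For oligodendrocyte genes, a lower share of the main cell type in the LNB sort therefore need not raise the list as far. Microglia genes differed less between the controls, but in the ENB and LNB sorts they had few counts. Their mean log2 CPM there was -0.11 and 0.27. The library index, added as a term, leaves a median of 3.44 of 3.94 and an adjusted list p of 6.3e-20, with adjusted p = 0.140 with an estimated correlation, which was 0.127 without the term, while genes called went from 13 to 2 and the median within ACTGCATA, with 1 LNB library, was 1.76. Expression of these genes by the neuroblasts themselves remains untested. The eYFP sort was meant to leave astrocytes out, though ensheathing and mural markers were higher in the same sort, at medians of 4.41 and 3.34. The first median is the value of Fabp7, which stands in both lists, so it is not separate from the genes above. Of the mural genes 1 of 7 was called, and the list's mean log2 CPM in LNB was 0.12.

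The 6 libraries of a comparison with 3 on each side allow 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 1772, 663 and 2580 genes at the 3 total mRNA steps and 1918 for LNB against the control, and the highest other split gave 0, 0, 27 and 0. Each other split mixes both groups on each side, so any difference between the groups widens its spread. Low counts there follow from that and add no support.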

How the results depend on the processing

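Among counts, the fit with all 27 libraries gave 3537, 1925 and 4311 genes at the 3 total mRNA steps, 562, 847 and 196 at the ribosome-bound steps, and 1482, 708 and 2632 for NSC, LNB and Neuron against the control. Fits of the compared groups only gave 4110, 203 and 1290 in total mRNA, 918, 5222 and 1406 in ribosome-bound mRNA, 1097 for the relative step NSC to ENB, and 102, 3326 and 1796 for ENB, LNB and Neuron against the control. DESeq2 gave 3358, 1891 and 3873 in total mRNA, 2914 and 1755 for ribosome-bound NSC to ENB and LNB to Neuron, 1568, 2263 and 1740 for the relative steps, and 863 and 3042 for ENB and LNB against the control. Without the expression filter the counts were 2400 and 1480 for ribosome-bound NSC to ENB and LNB to Neuron and 636 for ENB against the control. With limma on TPM they were 434 for ribosome-bound LNB to Neuron and 1108 for ENB against the control. Genes above the control in both stages left 212, 640 and 1 in ribosome-bound mRNA and 128 and 292 at the first 2 relative steps, and changed the Spearman correlations to 0.330, 0.147 and 0.359. At a mean log2 level of at least 5 these were 0.402, -0.026 and 0.486. Relative to each tissue's control, ENB to LNB had 76 genes in ribosome-bound mRNA and 637 as the relative step. The cause was not tested. Without the genes Gm42418 and CT010467.1, which overlap ribosomal RNA, the counts were 1752, 629 and 2381 in total mRNA, and the median change of all genes at the last of these steps went from -0.18 to -0.081.

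The second index as a term gave 155 genes for total ENB to LNB, 43 and 449 for the first 2 relative steps and 1176 for NSC against the control, and could not be estimated for relative LNB to Neuron. Within index ACTGCATA the total steps had 249, 4 and 758 genes, within GTAAGGAG the first had 770, within AGAGTAGA ribosome-bound NSC to ENB had 11 and NSC and ENB against the control 157 and 31, and within TATCCTCT ribosome-bound ENB to LNB had 7487 and LNB against the control 5826. Except for the last, at least 1 group in each of these fits holds 1 library, which was assumed to vary like the others.

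The replicate number as a block gave 205 genes for total ENB to LNB and 193 for ENB against the control and moved no other count by more than 1.5 times. Animal as a block gave 1217 for ribosome-bound ENB to LNB and 397 for the relative step.

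With 1 library left out the counts ranged from 721 to 892, 96 to 1643 and 1565 to 2337 in total mRNA, 354 to 962, 1271 to 1621 and 347 to 1199 in ribosome-bound mRNA, 56 to 459, 321 to 2302 and 78 to 845 at the relative steps, and 1050 to 3372, 1 to 224, 95 to 1842 and 2593 to 4772 for NSC, ENB, LNB and Neuron against the control. The correlations ranged from 0.199 to 0.255, -0.025 to 0.061 and 0.213 to 0.289. Where 1 library remained in a group it was assumed to vary like the others. Synapse genes in total NSC to ENB went from a median of -0.15 (adjusted p = 0.644) to -0.52 (adjusted p = 0.0237) without NSC replicate 2, the lowest, and -0.048 without NSC replicate 3, the highest. Pax6 in NSC against the control went from 0.31 (adjusted p = 0.740) to -2.08 (adjusted p = 0.0251) without NSC replicate 2 and 1.19 without NSC replicate 1, and Slc17a6 in ribosome-bound NSC to ENB from 5.34 (adjusted p = 0.0365) to -2.51 (adjusted p = 0.652) without ENB replicate 1 and 7.85 without NSC replicate 2. The groups of Slc17a6 overlap at this step. Depth, from 5225929 counts upward, limits what can be said of genes with few counts.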

Other observations

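Sox2 stood in total mRNA at 95.0 ± 10.6, 62.2 ± 13.6 and 83.0 ± 5.89 CPM in NSC, ENB and LNB, while in ribosome-bound mRNA it stood at 67.0 ± 26.95, 14.5 ± 2.74 and 33.3 ± 3.37 against 17.1 ± 2.73 and 19.8 ± 6.27 in the subventricular and bulb controls. Rps6, whose protein is part of the small subunit, went from 252 ± 24.9 in NSC to 89.7 ± 14.4 in Neuron total mRNA.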
